A study of Homo sapiens with 185 samples.

How the data were processed

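RNA sequencing of blood from children with a liver transplant gave 185 libraries, 75 taken before transplantation, 55 early after it and 55 late after it. Per the labels, the material was blood, described both as whole blood and as mononuclear cells, and total RNA was extracted with Trizol. The days between surgery and sampling, the treatment of each child and any rejection are not analysed here, because the labels used here give only the time of sampling.

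Per the submitters' processing notes, read quality was checked with FastQC 0.10.1, reads were aligned with STAR, genes were quantified with RSEM and the genome build was GRCh37. The versions of STAR and RSEM, the trimming, the strand setting and the library kit are not given in the sources used here. Each deposited gene file holds the authors' RSEM expected counts for 25343 gene symbols, in the same order in all libraries. Per the file headers, a column lists the transcripts of each gene, whose names are RefSeq identifiers. Expected counts share out reads that match several genes, and 8.87% of the values were not whole numbers. They were rounded to whole numbers before testing. The deposited isoform files and the TPM and FPKM columns were not used here. Gene symbols were compared with the RefSeq annotation of GRCh38.p14 for names only, and 24210 of the 25343 symbols matched by symbol or synonym. Because the authors used another build, no coordinates are given.

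The 108 genes of the Y chromosome, XIST and TSIX stayed in the library totals and were left out of every test and table. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 at its defaults for the 3 groups (minimum count 10), which left 15302 genes. Library sizes were scaled by TMM. The 3 groups were fitted together by edgeR's robust quasi-likelihood model in R 4.3.3. Each pair of groups was compared by its F test with Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05 and without a minimum fold. Standard errors of genes are the size of the log2 fold change divided by the square root of F. Values per group are CPM (counts per 1e6 counts) with their SD over libraries.

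File names carry 2 separate series of running numbers, which split the libraries into a first set of 65 and a second set of 120. The single file without a number was placed in the second set, because the number in its title lies in the range of that set. The sets may be technical batches. They differed in 6122 of the 15302 genes, each set holds all 3 groups, and the set was a covariate in the model. Within the first set there were 23 libraries from before, 18 from early after and 24 from late after transplantation, against 52, 37 and 31 in the second. No label ties samples of different times to a child, so nothing was paired, it is unknown which libraries share a child, and p-values measure only the spread between libraries. The closest pair of libraries correlated at 0.983 over genes, and counts of the closest pairs differed by at least 14.0 in chi-square per degree of freedom, so no library was treated as a repeat of another.

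A total of 30 gene lists with 471 entries, covering blood cell types, liver cells, interferon, rejection, immunosuppressant targets and general cell programmes, was written before the data were examined, as were the model, the alternatives and the rule for naming genes. Of the entries, 441 were tested, and lists with fewer than 5 tested members were not tested, which left 29. The lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with camera at an estimated correlation, and with fry. A score per library, the mean log2 CPM of a list's members, was compared between groups by a two-sided permutation test with 100000 resamples of the labels within set, in Python 3.11.15 with NumPy 2.4.6. These p-values were adjusted over 87 tests, 29 lists in 3 comparisons. A score difference is the mean of the differences within the 2 sets, weighted by their number of libraries. Its standard error comes from the SD of the 2 groups over all libraries. It ignores the sets and plays no part in the permutation test. The smallest p the permutations can give is 1e-05.

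Named genes are, for each comparison, the 7 highest and 7 lowest log2 fold changes among genes past the threshold with a mean log2 CPM above 2 and the same sign in both sets. A fixed panel of 15 genes is named whatever the result, and in each list that passes camera the members with the lowest adjusted p serve as examples. Any other gene named was chosen after its values were seen, and is said to be so where it appears. Some genes that this rule names are not reported here. Reads of near-identical copies (HBG1 and HBG2, FCGR1A to FCGR1C) can be shared out wrongly, and reads on small nucleolar RNA genes can come from the host transcripts that contain them.

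Simulated negative binomial counts with the real means, dispersions, sets and library sizes tested the model of early after against before on 15302 genes, with 200 genes changed in each of 3 runs. Of the changed genes, 47.8% were recovered at a fold of 1.25, 78.1% at 1.5 and 96.0% at 2, and 6.34% of the calls were false. For the list scores of that comparison, simulated shifts of 0.8 SD were recovered in 98.0% of cases, with 4.0% false calls. The simulated genes were independent of each other, unlike genes in blood.

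Total counts per library ranged from 295514 to 29334633, with a median of 9578942, and 28 libraries lay below 0.5 of that median. Alternatives covered the scaling (RLE), the tool (DESeq2 1.42.0, limma-voom), the filter, the covariates, each set alone, haemoglobin genes, shallow libraries and the library without a number. Added after seeing the data were fits without libraries above 300 CPM on olfactory receptor genes, with that level as a covariate, and without libraries above 10% haemoglobin.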

Results

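Gene expression in blood was measured by RNA sequencing in children with a liver transplant, in 75 libraries from before transplantation, 55 from early after it and 55 from late after it. The values were estimated read counts for 25343 genes per library, of which 15302 had enough counts to be tested. The 3 times were compared pairwise to show how the blood transcriptome differed between them. Rejection was not analysed here, and age at sampling was not in the model. The labels describe the material both as whole blood and as mononuclear cells, and in mononuclear cells the neutrophil and red cell results below would reflect carried-over or low-density cells. The mature neutrophil score, the mean log2 CPM of its genes, averaged 7.26 before, 7.46 early and 7.43 late. That of classical monocytes averaged 7.15, 7.42 and 7.13. This argues against material free of neutrophils, but does not separate whole blood from mononuclear cells with many neutrophils. The labels do not tie libraries of different times to a child, so p-values measure the spread between these libraries, which may in part be technical, and their independence is unknown.

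Total counts per library ranged from 295514 to 29334633. The median was 9077225 before, 10415299 early after and 9487051 late after transplantation. Below 0.5 of the median of all libraries lay 13 libraries from before, 7 from early after and 8 from late after transplantation. Counts on 378 olfactory receptor genes, which blood cells are not known to express as a class, exceeded 300 CPM (counts per 1e6 counts) in 24 libraries, 22 of them among those with low totals. Haemoglobin genes took between 0.0133% and 87.4% of the counts, with medians of 0.759% before, 0.801% early and 0.647% late. Within the first set these were 0.541%, 0.654% and 1.92%, and within the second 2.44%, 0.870% and 0.262%. They took more than 10% in 10, 7 and 3 libraries of the 3 times. Most of these libraries lay in the second set. That held for all of those from before, since the highest share in the first set before transplantation was 2.44%. File numbering split the libraries into a first set of 65 and a second set of 120, which differed in 6122 genes. The set was part of the model, and values within each set are given below for part of the results.

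**Figure D1:**
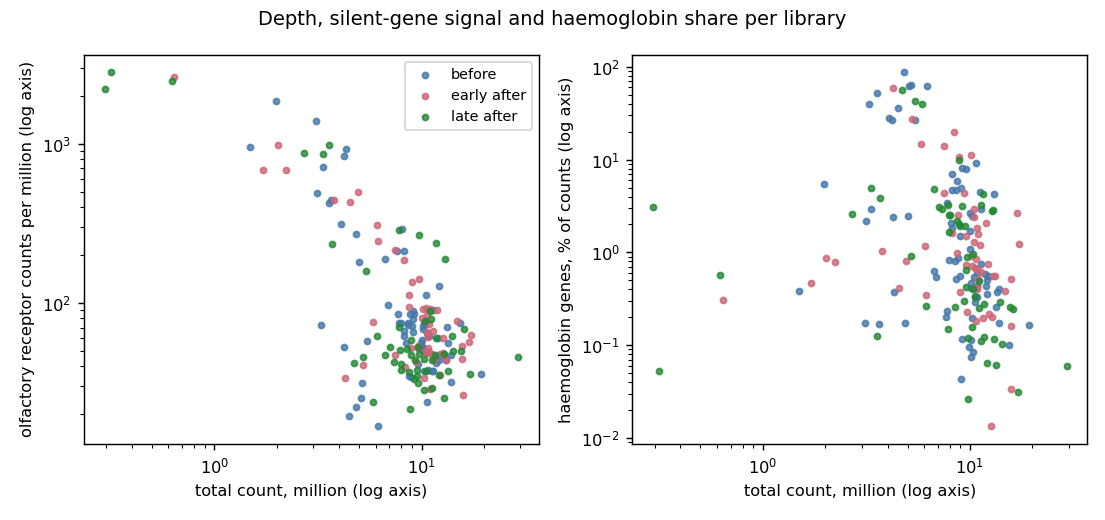
Each point is 1 library, with its total count (log axis) against the summed CPM of olfactory receptor genes (left, log axis) and against the percent of counts on haemoglobin genes (right, log axis), coloured by time. Of the 24 libraries above 300 CPM on olfactory receptor genes, 22 had a total below 0.5 of the median. Libraries with more than 10% haemoglobin came from all 3 times, but mostly from the second set.

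Early after transplantation, the T cell score was lower and the interferon, granule and platelet scores were higher than before. Camera with an estimated correlation called none of these lists. Fry, which does not compare a list with other genes, gave adjusted p = 5.77e-05 for the T cell and 2.55e-06 for the interferon gamma list. For the type I interferon list fry gave 0.0193, for the granule list 0.000107 and for the platelet list 5.05e-05. By fry the common rejection (0.191) and fetal haemoglobin (0.233) lists did not pass, although their scores did. GBP5, an interferon-induced GTPase, rose by 1.36 ± 0.21 on the log2 scale (SE; adjusted p = 6.36e-07; 734 ± 958 against 285 ± 288 CPM, SD, n = 55 and 75), by 1.96 in the first set and 1.11 in the second. The platelet integrin genes ITGB3 and ITGA2B rose by 1.39 ± 0.24 and 1.38 ± 0.26. CCR9, a chemokine receptor for homing to the gut, fell by 1.14 ± 0.15 (adjusted p = 4.46e-08), from 9.07 ± 5.33 to 4.13 ± 3.02 CPM, and only 5 of 55 early libraries lay above the median from before. GPR15, another gut-homing receptor of T cells, fell by 1.12 ± 0.16 (adjusted p = 7.48e-08). In edgeR's quasi-likelihood test 3291 genes changed, 1636 higher and 1655 lower, and 454 of them differed by at least 1.5-fold, 326 higher and 128 lower. The share of higher genes was 49.7%, against 46.6% with limma-voom and 53.4% with haemoglobin genes left out.

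Other genes with the highest fold changes were GBP6 (1.48), the complement inhibitor gene SERPING1 (1.41), the carbonic anhydrase gene CA1 of red cells (1.33) and the Fc receptor gene FCGR1C (1.30), whose reads can be confused with those of FCGR1A and FCGR1B. CA1 passed in neither set alone (adjusted p = 0.0642 and 0.0779). In the second set alone SERPING1 (adjusted p = 0.0636) and FCGR1C (0.0808) did not pass. Among the lowest were the plasma cell receptor gene TNFRSF17 (-1.02) and the small RNA genes SNORD10 (-1.08), SNORD94 (-1.05) and SCARNA21 (-0.98). HBG2, a fetal haemoglobin gene nearly identical to HBG1, was lowest at -2.15 ± 0.64 (adjusted p = 0.00906), but at -0.11 in the first set and -2.64 in the second.

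Of 18 T cell genes, 13 fell and 5 did not pass, and 16 fell when adjusted over the list alone. IL7R, the interleukin 7 receptor, fell by 0.85 ± 0.12, TCF7 by 0.53 ± 0.11 and CD3E by 0.50 ± 0.11. The T cell score, the mean log2 CPM of the list, was lower by -0.47 ± 0.12 (adjusted p = 0.000507, two-sided permutation test), -0.82 in the first set and -0.31 in the second, and 12 of 55 early libraries lay above the median from before. Of 14 naive T cell genes, 10 fell, also when adjusted over the list alone, among them CCR7 (-0.72) and LRRN3 (-0.87), with a score difference of -0.41 ± 0.08 (adjusted p = 0.000174). Among 12 plasma cell genes, 4 fell and 1 rose, with 7 and 1 when adjusted over the list alone, and the antibody chain gene IGJ was at -0.94 ± 0.31. The plasma cell score was lower by -0.38 ± 0.15 (adjusted p = 0.0254). With an estimated correlation between genes, the camera test gave an adjusted p = 0.144 for the T cell, 0.107 for the naive T cell and 0.444 for the plasma cell list. CD8A, a cytotoxic T cell gene, was higher by 0.46 ± 0.14 (adjusted p = 0.0135), but at -0.20 in the first set and 0.73 in the second. In the dendritic cell list the plasmacytoid genes LILRA4 (-0.62) and CLEC4C (-0.64) fell while FLT3, which progenitors also express, rose (0.88). This list's score was lower by -0.25 ± 0.08 (adjusted p = 0.00535), and camera gave an adjusted p = 0.381 with an estimated correlation.

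Of 17 interferon gamma genes, 15 rose, also when adjusted over the list alone, among them GBP1 (1.21), GBP2 (0.72) and the chemokine gene CXCL10 (1.15 ± 0.28). Their score was higher by 0.58 ± 0.11 (adjusted p = 0.000174; 0.73 and 0.50 in the sets), and 48 of 55 early libraries lay above the median from before. Among 20 type I interferon genes, 10 rose and 16 when adjusted over the list alone, including EPSTI1 (0.91) and IFI44L (0.91 ± 0.34), with a score difference of 0.61 ± 0.25 (adjusted p = 0.0267). IFI44L was at 1.62 in the first set and 0.56 in the second, where it did not pass (adjusted p = 0.500). Camera gave adjusted p = 0.107 for the interferon gamma and 0.422 for the type I list with an estimated correlation.

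Of 18 granule genes of immature neutrophils, 9 rose, and 11 when adjusted over the list alone, for example CAMP (1.22), which encodes an antimicrobial peptide, RNASE3 (1.09) and CEACAM8 (1.08 ± 0.34). CEACAM8 was at 2.18 in the first set and 0.50 in the second, where it did not pass (adjusted p = 0.581). Their score was higher by 1.10 ± 0.26 (adjusted p = 0.000507; 1.39 and 0.97 in the sets). In the platelet list 14 of 16 genes rose, and 15 when adjusted over the list alone, led by MYL9 (1.45) and with the chemokine gene PPBP at 1.07 ± 0.20, and the score was higher by 0.78 ± 0.18 (adjusted p = 0.000507; 1.10 and 0.63 in the sets). With an estimated correlation, the adjusted p of camera was 0.144 for both of these lists. Of 18 erythroid genes, 5 rose, and 8 when adjusted over the list alone, with EPB42 at 0.89 and the haem synthesis gene ALAS2 at 0.86 ± 0.32. ALAS2 passed in neither set alone (adjusted p = 0.184 and 0.254). The erythroid score was higher by 0.78 ± 0.30 (adjusted p = 0.0267; 1.21 and 0.58 in the sets), and camera gave an adjusted p = 0.422 with an estimated correlation. In the second set the median haemoglobin share went the other way, from 2.44% before to 0.870% early. The monocyte scavenger receptor gene CD163 rose by 1.05 ± 0.18, at 1.92 in the first set and 0.56 in the second. It belongs to the classical monocyte list, and the classical monocyte score was higher by 0.26 ± 0.11 (adjusted p = 0.0375), with 4 of 12 genes up, 1 down and the same counts when adjusted over the list alone (adjusted p = 0.422 with an estimated correlation). CD14 itself was at 0.09 ± 0.14. FCGR3B was the only 1 of 16 mature neutrophil genes to pass (0.60 ± 0.17), and that score did not pass (adjusted p = 0.332), although camera called the list (adjusted p = 0.042, and 0.760 with an estimated correlation).

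Smaller shifts were found in general programmes. Of 16 cholesterol synthesis genes 9 rose, and 11 when adjusted over the list alone, with CYP51A1 at 0.29, and the score was higher by 0.20 ± 0.05 (adjusted p = 0.000819; 0.144 for camera with an estimated correlation). Cell cycle genes rose in 10 of 20 cases, and in 12 when adjusted over the list alone, with MKI67 at 0.78 ± 0.20 and TPX2 at 0.73, and the score was higher by 0.36 ± 0.16 (adjusted p = 0.0488; 0.433 for camera with an estimated correlation). Glucocorticoid response genes rose in 6 of 12 cases, and in 7 when adjusted over the list alone. TSC22D3 (0.49) and FKBP5 (0.54 ± 0.17), both induced by steroids, were among them, and the score was higher by 0.28 ± 0.12 (adjusted p = 0.0246), at 0.74 in the first set and 0.07 in the second (adjusted p = 0.422 for camera with an estimated correlation). FKBP5 was at 1.34 in the first set and 0.11 in the second, where it did not pass (adjusted p = 0.827). Among immediate early genes, KLF6 (0.40) and ATF3 (1.06) rose. Their score was higher by 0.22 ± 0.09 (adjusted p = 0.0206), with 7 of 14 genes up, and 9 up and 1 down when adjusted over the list alone (adjusted p = 0.381 for camera with an estimated correlation). Inflammatory cytokine genes rose in 3 of 14 cases, and in 6 when adjusted over the list alone, with a score difference of 0.24 ± 0.09 (adjusted p = 0.0254; 0.422 for camera with an estimated correlation). Of 32 ribosomal protein genes 12 fell, and 16 when adjusted over the list alone, such as RPS28 (-0.50), and the score was lower by -0.25 ± 0.11 (adjusted p = 0.0435; 0.422 for camera with an estimated correlation). The common rejection module, a set of genes raised in rejected grafts, had a score higher by 0.15 ± 0.06 (adjusted p = 0.0347), with 3 genes up and 1 down of 11, and 3 and 2 when adjusted over the list alone. Camera did not call this list (adjusted p = 0.338, and 0.699 with an estimated correlation). The B cell gene MS4A1 (0.18 ± 0.18), the cytotoxic gene NKG7 (-0.00 ± 0.19) and the interleukin 2 receptor gene IL2RA (0.18 ± 0.09) did not pass.

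In all, 18 of 29 list scores passed, 12 higher and 6 lower, and 17 of them had the same sign in both sets. The exception was fetal haemoglobin, at -0.50 ± 0.22 (adjusted p = 0.0474), with 0.07 in the first set and -0.76 in the second, a median fold of 0.07 and a mean of -0.59 over its 5 members, and camera did not call it (adjusted p = 0.470, and 0.746 with an estimated correlation). Median and camera direction differed for the cytotoxic (0.07, down), B cell (0.05, down), non-classical monocyte (-0.15, up), regulatory T cell (0.08, down) and calcineurin (0.10, down) lists, none of which passed. None of the 13 hepatocyte genes had enough counts to be tested. Camera with a preset correlation called 17 lists, but reshuffled labels gave up to 20, and 0 were called with an estimated correlation, so list statements rest on the scores and on single genes. In the second set alone 670 genes passed, against 2170 in the first.

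**Figure D2:**
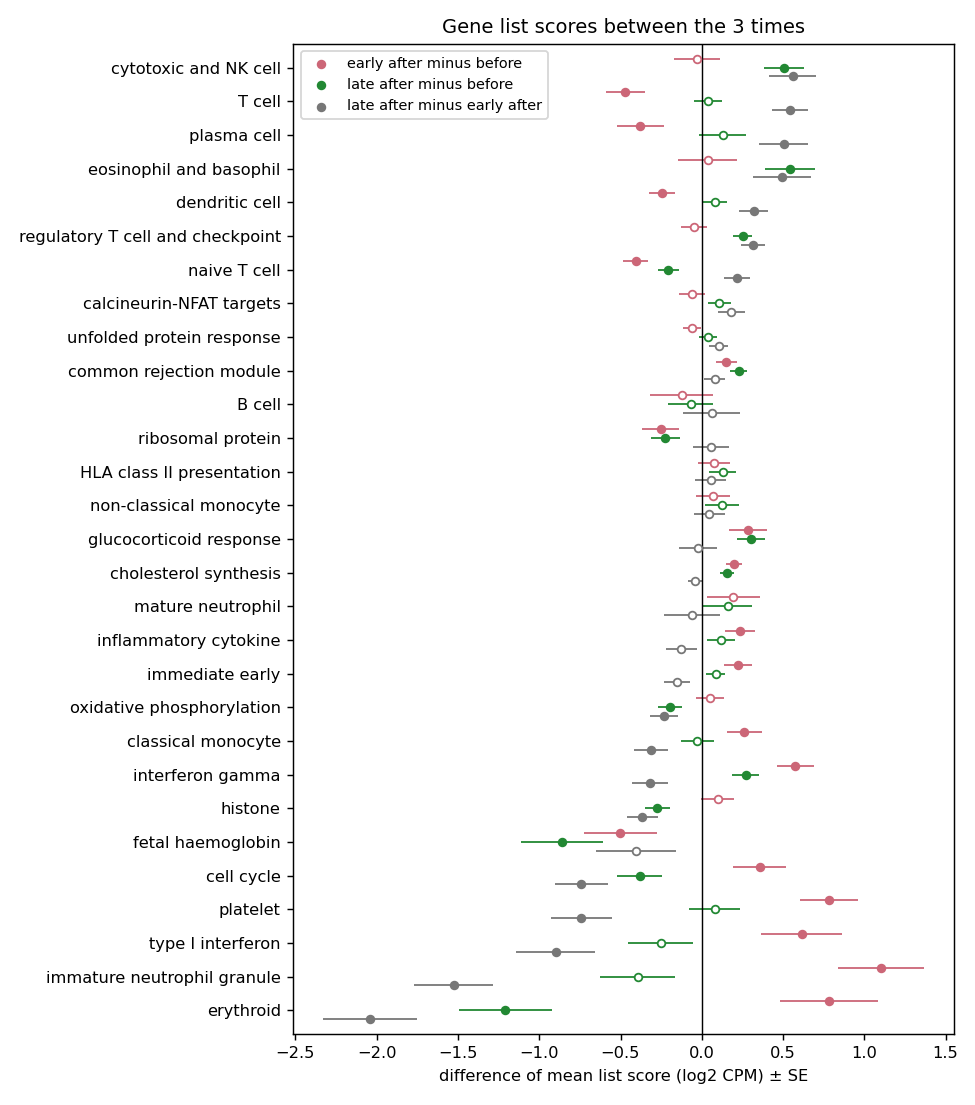
Differences in list score (mean log2 CPM of the members) between the 3 times, with SE as bars, for 29 gene lists, where filled points mark an adjusted p under 0.05 in the permutation test and open points do not. The erythroid score was higher early than before by 0.78 and lower late than before by -1.21.

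Late after transplantation, red cell genes were lower and cytotoxic genes were higher than before, and single granule genes fell although their list score did not pass. The share of counts on haemoglobin genes did not follow the red cell list in the first set, where its median was 0.541% before and 1.92% late. CA1 fell by 2.52 ± 0.39 (adjusted p = 3.47e-07), from 431 ± 673 to 76.1 ± 148 CPM (SD, n = 75 and 55), by 3.21 in the first set and 2.15 in the second. The interferon-induced gene IFI27 fell by 2.82 ± 0.54 (adjusted p = 2.67e-05) and CTSG, a protease of neutrophil granules, by 2.16 ± 0.39. PTPN13, a tyrosine phosphatase gene, rose by 1.01 ± 0.13 (adjusted p = 8.41e-09), with 54 of 55 late libraries above the median from before, and GZMH, a granzyme of cytotoxic cells, by 1.03 ± 0.24. GZMH passed in neither set alone (1.08 and 0.91, adjusted p = 0.0558 and 0.0559). In the same test 3131 genes changed, 1230 higher and 1901 lower, and 653 differed by at least 1.5-fold, 157 higher and 496 lower. The share of higher genes was 39.3% here and 53.6% with limma-voom.

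Among the other highest genes were MYO6 (1.15), the lymphocyte receptor gene FCRL6 (1.12), KIF21A (1.07), JAKMIP1 (1.05) and the tryptophan-degrading enzyme gene IDO1 (1.05). Among the lowest were RAP1GAP (-2.48), MAOA (-2.21), PAGE2B (-2.13) and AHSP (-2.15), whose product chaperones alpha globin. RAP1GAP was at -4.21 in the first set and -1.68 in the second, and MAOA at -4.51 and -0.90.

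Of 18 erythroid genes 17 fell, and all 18 when adjusted over the list alone, with XK at -2.06 and ALAS2 at -1.15 ± 0.33. The erythroid score was lower by -1.21 ± 0.28 (adjusted p = 0.000559; -1.45 and -1.07 in the sets), and 10 of 55 late libraries lay above the median from before. Granule genes of immature neutrophils fell in 13 of 18 cases, and in 15 when adjusted over the list alone, with MPO at -2.02, ELANE at -1.98 and CEACAM8 at -1.12 ± 0.36. Medians differed less than these folds, with MPO at 2.14 CPM late and 3.12 before, ELANE at 0.484 and 0.595 and CEACAM8 at 2.50 and 3.36. Above the median from before lay 16, 23 and 24 of 55 late libraries, and CEACAM8 passed in neither set alone. The granule score, however, differed by -0.39 ± 0.23 and did not pass (adjusted p = 0.187). In the fetal haemoglobin list IGF2BP3, an RNA-binding protein gene of fetal tissue, fell by 1.16 ± 0.14, the only 1 of 5 to pass, also when adjusted over the list alone, and the score was lower by -0.86 ± 0.25 (adjusted p = 0.00248). The globin genes HBG2 (-1.36 ± 0.68) and HBG1 (-0.76 ± 0.76) did not pass, and they were at 1.05 and 2.80 in the first set (adjusted p = 0.442 and 0.00982) and both at -2.52 in the second. With an estimated correlation, camera gave an adjusted p = 0.322 for the erythroid, 0.666 for the granule and 0.322 for the fetal haemoglobin list.

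Of 20 cytotoxic and NK cell genes 13 rose, and 15 when adjusted over the list alone, among them the transcription factor genes EOMES (0.80) and TBX21 (0.73), the receptor gene KLRD1 (0.78) and NKG7 (0.68 ± 0.19). The score was higher by 0.51 ± 0.12 (adjusted p = 0.000535; 0.83 and 0.32 in the sets; 0.322 for camera with an estimated correlation), and 45 of 55 late libraries lay above the median from before. The checkpoint genes TIGIT (0.94), LAG3 (1.27) and PDCD1 (0.86) rose and RTKN2 fell (-0.50) in the regulatory T cell and checkpoint list of 11 genes. When adjusted over the list alone the same 3 and 1 passed. LAG3 and PDCD1 had few counts, with means of 1.17 and 2.18 CPM late against 0.559 and 1.24 before. LAG3 did not pass in the second set alone (0.86, adjusted p = 0.165), and RTKN2 passed in neither (adjusted p = 0.0527 and 0.107). The score of this list was higher by 0.25 ± 0.06 (adjusted p = 0.000507, and 0.393 for camera with an estimated correlation). Eosinophil and basophil genes rose in 6 of 12 cases, and in 7 when adjusted over the list alone, such as IL5RA (0.91) and PRSS33 (0.93), with a score difference of 0.54 ± 0.16 (adjusted p = 0.00417; 0.393 for camera with an estimated correlation). Of 14 naive T cell genes 5 fell, and 7 when adjusted over the list alone, with LRRN3 at -0.73, and the score was lower by -0.21 ± 0.06 (adjusted p = 0.0055; 0.393 for camera with an estimated correlation). The T cell score did not pass (0.04 ± 0.09, adjusted p = 0.762), nor did CD3E (-0.15 ± 0.11), CD8A (0.33 ± 0.15) or MS4A1 (-0.35 ± 0.18).

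Interferon gamma genes rose in 3 of 17 cases and fell in 1, also when adjusted over the list alone, with PSMB10 at 0.31 and SOCS1 at -0.46, and the score was higher by 0.27 ± 0.08 (adjusted p = 0.00655; 0.418 for camera with an estimated correlation). The type I interferon score did not pass (-0.25 ± 0.20, adjusted p = 0.332), although IFI44L fell by 0.94 ± 0.35. IFI44L passed in neither set alone (adjusted p = 0.458 and 0.177), with medians of 60.3 CPM late and 79.7 before. The common rejection module had 4 of 11 genes up, also when adjusted over the list alone, with RUNX3 at 0.24 and CD6 at 0.31, and a score higher by 0.23 ± 0.05 (adjusted p = 0.000507; 0.322 for camera with an estimated correlation). It overlaps other lists, since NKG7 is also in the cytotoxic list and CD6 in the T cell list. By set RUNX3 was at 0.45 and 0.09 and CD6 at 0.34 and 0.25, and only RUNX3 in the first set passed. Glucocorticoid response genes rose in 3 of 12 cases, also when adjusted over the list alone, with SGK1 at 0.36, and the score was higher by 0.30 ± 0.08 (adjusted p = 0.00257; 0.393 for camera with an estimated correlation), while FKBP5 was at 0.10 ± 0.17. Cholesterol synthesis genes rose in 4 of 16 cases, also when adjusted over the list alone, with LSS at 0.37, and the score was higher by 0.15 ± 0.04 (adjusted p = 0.00519; 0.393 for camera with an estimated correlation).

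Cell cycle genes fell in 9 of 20 cases, and in 10 when adjusted over the list alone, led by AURKA (-0.82), with a score difference of -0.38 ± 0.14 (adjusted p = 0.0189; 0.418 for camera with an estimated correlation), and MKI67 was at -0.33 ± 0.20. Of 15 histone genes 5 fell, and 7 when adjusted over the list alone, with H1F0 at -1.17 and a score difference of -0.27 ± 0.08 (adjusted p = 0.00519; 0.393 for camera with an estimated correlation). Oxidative phosphorylation genes fell in 10 of 25 cases, and in 11 when adjusted over the list alone, with UQCRB at -0.66 and a score difference of -0.20 ± 0.07 (adjusted p = 0.0241; 0.586 for camera with an estimated correlation). Ribosomal protein genes fell in 10 of 32 cases, and in 18 when adjusted over the list alone, with RPS24 at -0.81 and a score difference of -0.22 ± 0.09 (adjusted p = 0.0375; 0.637 for camera with an estimated correlation). IGJ (-0.16 ± 0.30), CD14 (0.12 ± 0.14), FCGR3B (0.19 ± 0.17), PPBP (0.32 ± 0.20), IL2RA (0.02 ± 0.10) and CXCL10 (0.08 ± 0.29) did not pass.

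A total of 14 of 29 scores passed late against before, 7 higher and 7 lower, all 14 with the same sign in both sets. Camera called 15 lists, against up to 18 with reshuffled labels and 0 with an estimated correlation. Fry gave adjusted p = 0.000741 for the erythroid, 0.000746 for the cytotoxic and 0.170 for the granule list. By fry the ribosomal protein (0.121) and oxidative phosphorylation (0.0838) lists did not pass, although their scores did. Median and camera direction differed for the non-classical monocyte (-0.01, up) and immediate early (-0.04, up) lists, which did not pass. With the erythroid score in the model 1947 genes passed, and 1264 and 1098 passed in the first and second set alone.

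Between early and late after transplantation, the red cell, granule, interferon and cell cycle scores were lower late, and the T cell and cytotoxic scores were higher. Camera with an estimated correlation called none of these lists. Small nucleolar RNA genes, which were not one of the lists written in advance, were mostly higher late. CA1 fell by 3.85 ± 0.42 (adjusted p = 2.51e-13), a 14.4-fold difference, with 2 of 55 late libraries above the early median. PTPN13 rose by 1.77 ± 0.15 (adjusted p = 2.68e-20) and all 55 late libraries lay above the early median. GPR15 rose by 1.48 ± 0.17 (adjusted p = 9.35e-13), from 3.49 ± 2.29 to 10.1 ± 8.28 CPM (SD, n = 55 and 55). In this comparison 6473 genes changed, 2867 higher and 3606 lower, and 1574 differed by at least 1.5-fold, 472 higher and 1102 lower. The share of higher genes was 44.3% here and 53.5% with limma-voom, so which direction held more genes depended on the tool.

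The highest fold changes included the small nucleolar RNA genes SNORA64 (2.25), SNORD94 (1.76), SNORD10 (1.63), SNORA63 (1.51) and SNORA78 (1.51), which guide the modification of other RNAs and lie in introns of host genes. SNORA64 was at 0.48 in the first set and 3.31 in the second, and SNORA63 at 0.44 and 2.15, and neither passed in the first set alone. The lowest included IFI27 (-3.67 ± 0.58), RAP1GAP (-3.46), AHSP (8.01-fold lower), MAOA (-2.91), CTSG (-2.82) and IFIT1B (-2.82).

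All 18 erythroid genes fell, also when adjusted over the list alone, with BPGM at -2.82 and ALAS2 at -2.01 ± 0.36. The erythroid score was lower by -2.04 ± 0.29 (adjusted p = 0.000174; -2.67 and -1.65 in the sets), and 5 of 55 late libraries lay above the early median. In the first set the median haemoglobin share went the other way, from 0.654% early to 1.92% late. Of 18 granule genes of immature neutrophils 17 fell, also when adjusted over the list alone, with ELANE at -2.43 and CEACAM8 at -2.20 ± 0.38, and the score was lower by -1.53 ± 0.24 (adjusted p = 0.000174; -1.78 and -1.37 in the sets). Platelet genes fell in 13 of 16 cases, also when adjusted over the list alone, with GNG11 at -1.28 and PPBP at -0.76 ± 0.21, and the score was lower by -0.74 ± 0.19 (adjusted p = 0.000816; -1.23 and -0.44 in the sets). In the second set alone PPBP did not pass (-0.45, adjusted p = 0.250). Classical monocyte genes fell in 7 of 12 cases, also when adjusted over the list alone, with CD163 at -1.13 and CD14 at 0.03 ± 0.15, and the score was lower by -0.31 ± 0.10 (adjusted p = 0.00654). With an estimated correlation camera gave an adjusted p = 0.572 for each of these 4 lists.

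All 20 type I interferon genes fell, also when adjusted over the list alone, such as EPSTI1 (-1.27) and IFI44L (-1.85 ± 0.37), with a score difference of -0.90 ± 0.24 (adjusted p = 0.0016; -1.16 and -0.74 in the sets). Of 17 interferon gamma genes 11 fell, and 11 fell and 1 rose when adjusted over the list alone, with GBP1 at -1.12, SOCS1 at -1.18 and CXCL10 at -1.07 ± 0.31, and the score was lower by -0.32 ± 0.11 (adjusted p = 0.0163). All 20 cell cycle genes fell, also when adjusted over the list alone, with TPX2 at -1.47 and MKI67 at -1.11 ± 0.22, and the score was lower by -0.74 ± 0.16 (adjusted p = 0.000373). Histone genes fell in 10 of 15 cases, also when adjusted over the list alone, with H1F0 at -1.60 and a score difference of -0.37 ± 0.10 (adjusted p = 0.000696). Camera with an estimated correlation gave an adjusted p = 0.572 for these 4 lists too. Oxidative phosphorylation genes fell in 14 of 25 cases and rose in 1, with 15 and 1 when adjusted over the list alone, UQCRB at -0.86 and a score difference of -0.23 ± 0.08 (adjusted p = 0.0189; 0.575 for camera with an estimated correlation).

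T cell genes rose in 13 of 18 cases, and in 14 when adjusted over the list alone, with IL7R at 0.95, CD6 at 0.79 and CD3E at 0.35 ± 0.12, the last at 0.89 in the first set and 0.00 in the second (adjusted p = 0.991). The T cell score was higher by 0.54 ± 0.11 (adjusted p = 0.000174), at 0.97 in the first set and 0.28 in the second. Cytotoxic and NK cell genes rose in 9 of 20 cases, also when adjusted over the list alone, with KLRB1 at 1.19 and NKG7 at 0.69 ± 0.20, and the score was higher by 0.56 ± 0.14 (adjusted p = 0.00106; 0.99 and 0.29 in the sets). Plasma cell genes rose in 6 of 12 cases, and in 7 when adjusted over the list alone, with TXNDC5 at 0.97 and IGJ at 0.78 ± 0.33, and the score was higher by 0.50 ± 0.15 (adjusted p = 0.00356). Eosinophil and basophil genes rose in 7 of 12 cases, also when adjusted over the list alone, with ALOX15 at 1.07, and the score was higher by 0.49 ± 0.18 (adjusted p = 0.0198). In the regulatory T cell and checkpoint list TIGIT (0.97) and IKZF2 (0.49) rose, 2 of 11 genes also when adjusted over the list alone, and the score was higher by 0.31 ± 0.07 (adjusted p = 0.00029). For these 5 lists camera gave an adjusted p = 0.572 with an estimated correlation. The naive T cell score (0.22 ± 0.08, adjusted p = 0.0172) and the dendritic cell score (0.32 ± 0.09, adjusted p = 0.00253) were also higher, although camera did not call these lists. The B cell gene MS4A1 was at -0.54 ± 0.19 and FKBP5 at -0.44 ± 0.18, both past the threshold, but FKBP5 was at -1.10 in the first set and -0.01 in the second (adjusted p = 0.981). FCGR3B (-0.40 ± 0.18), IL2RA (-0.16 ± 0.10) and CD8A (-0.13 ± 0.16) did not pass. In the sets alone CD8A passed in opposite directions, at 0.67 in the first (adjusted p = 0.0112) and -0.57 in the second (adjusted p = 0.0322).

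Of 29 scores 16 passed, 7 higher and 9 lower, all 16 with the same sign in both sets. Camera called 14 lists, against up to 15 with reshuffled labels and 0 with an estimated correlation. Median and camera direction differed for the B cell (-0.27, up), glucocorticoid (-0.29, up), common rejection (-0.12, up), HLA class II (-0.04, up), non-classical monocyte (-0.05, up) and ribosomal (-0.02, up) lists, none of which passed. The B cell, HLA class II, mature neutrophil, non-classical monocyte, calcineurin and unfolded protein response scores passed in none of the 3 comparisons. In the second set alone 3964 genes passed, and with the erythroid score in the model camera called 9 lists.

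**Figure D3:**
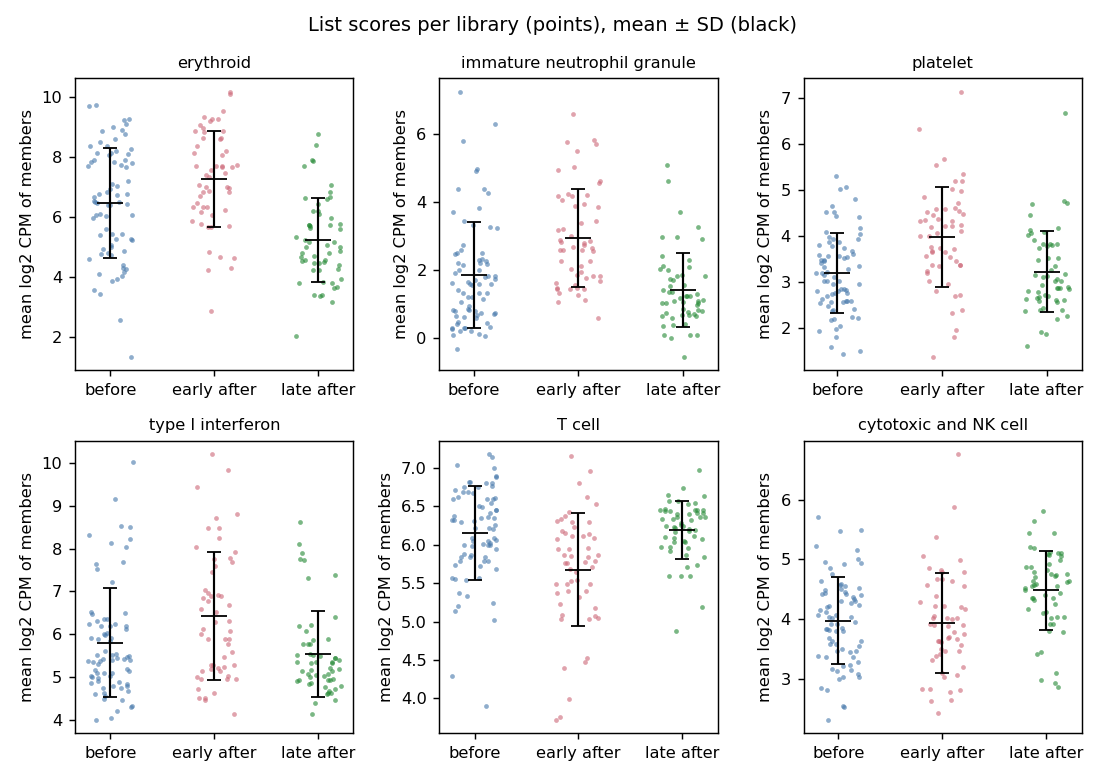
List scores (mean log2 CPM of the members, 1 point per library) for 6 lists at the 3 times, with mean and SD in black. The erythroid score averaged 6.48 before, 7.26 early and 5.22 late, and the T cell score 6.15, 5.68 and 6.19.

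Genes that changed against before at both later times were compared directly. Of the 15302 genes, 181 changed in the same direction early and late, 85 higher and 96 lower, against 132 and 206 for independent lists. In opposite directions 532 changed, against 336 for independent lists, of which 276 were higher early and lower late. Across genes, which are not independent replicates, the 2 sets of fold changes correlated at -0.160 with a covariance of -0.0122. Both comparisons share the libraries from before, and 8 simulations of unchanged groups gave a mean correlation of 0.419, a covariance of 0.0115 and 0 shared genes. The observed covariance lay -0.0236 from the simulated one, but the simulated genes were independent of each other, so that gap lacks a realistic spread. Labels reshuffled within set 20 times keep the correlation between genes. Their covariance averaged 0.0201 (SD 0.0200) and ranged from 0.00249 to 0.0726. With the libraries from before split between the comparisons (8 draws), a median of 45 genes changed in the same direction and 392 in opposite directions, and the mean correlation was -0.302. Independent lists of the lengths in these draws would give medians of 180 and 177. The median fold change was 0.47 early and -1.36 late for erythroid genes, and 0.80 and -1.09 for granule genes, whose list score did not pass late against before (-0.39 ± 0.23).

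**Figure D4:**
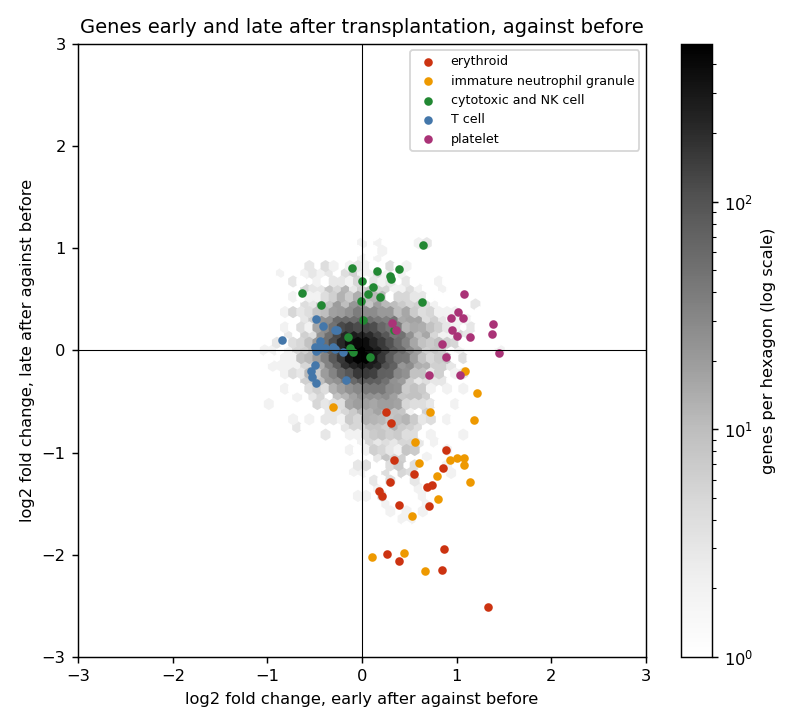
Log2 fold changes of all tested genes early (x axis) and late (y axis) against before transplantation, both from -3 to 3, with grey hexagons shaded by number of genes on a log scale and coloured points for the members of 5 lists. Across genes the correlation was -0.160, and the median erythroid gene lay at 0.47 early and -1.36 late.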

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

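The tests of haemoglobin genes, haemoglobin-rich libraries, low library totals, the erythroid score, the set for small nucleolar RNA genes, and CCR9 and GPR15 against the T cell scores were chosen only after the result was seen. Labels were reshuffled within set 20 times, so each result was compared over 21 splits, the real one included.

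The number of changed genes was as large in 1 of 21 splits, the real one, for each comparison, which is the smallest share that 21 splits can give. Reshuffling treats libraries as exchangeable, and it is unknown which libraries share a child. The shares argue against chance only under that assumption, and they were not adjusted for the 3 comparisons. Early against before, 3291 genes changed, and the highest other splits gave 1207 and 655. What those splits have in common was not tested. Late against before, 3131 genes changed against 8 in the highest other split, and late against early 6473 against 22. For the 181 genes changed in the same direction at both times, 1 of 21 splits, the real one, gave as many and the highest other gave 1. This says nothing about sharing, because reshuffled labels called a median of 0 genes in each comparison, and independent lists of the real lengths would share 132 higher and 206 lower genes. For the lists called by camera chance cannot be excluded, since 3 of 21 splits called at least 17 lists early (highest other 20), 3 of 21 at least 15 late (highest other 18) and 2 of 21 at least 14 late against early (highest other 15).

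A difference between the 2 file sets drew attention to some genes. By a test of the interaction, 3 genes differed between the sets early against before, 7 late against before and 227 late against early. Of these, 0%, 71.4% and 52.4% were also called in the respective comparison, where 3291, 3131 and 6473 of all 15302 genes were called. The interaction test gave an unadjusted p under 0.05 for 1472, 890 and 2796 genes, so weaker differences between the sets may be more widespread. No list score differed between the sets past the threshold. The lowest p was for the T cell score late against early, where the second set lay -0.69 ± 0.22 from the first (adjusted p = 0.160).

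Erythroid, immature neutrophil granule and cell cycle scores were lower late than early by -2.03 ± 0.32, -1.52 ± 0.27 and -0.75 ± 0.16 in the linear model of these tests. The smallest of the 3 stayed at -0.742 ± 0.161 with haemoglobin genes left out, at -0.728 ± 0.169 without libraries above 10% haemoglobin and at -0.824 ± 0.179 without libraries of low total, which argues against each of these as the whole cause. With the erythroid score in the model the immature neutrophil score was still lower by -1.07 ± 0.29 and the cell cycle score by -0.575 ± 0.176. This argues against a linear effect of the erythroid score as the whole cause. The score only approximates the erythroid share, so a change of that share alone is not excluded. No other biological explanation was tested. The time since surgery, treatment and sample handling stay open, and age at sampling was not in the model.

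Small nucleolar RNA genes, which were not one of the lists written in advance, were mostly higher late than early. Of 82 tested, 66 passed as higher and 2 as lower, with a median of 0.91. Early against before 1 rose and 39 fell, with a score difference of -0.44 ± 0.13, and late against before 24 rose and 3 fell, with a score difference of 0.20 ± 0.13 that lies within 2 standard errors of 0. The difference in their score late against early, 0.64 ± 0.14, was 0.662 ± 0.147 without libraries of low total and at least 0.501 ± 0.165 in each set alone. This argues against low totals and the set as the whole cause. With the T cell score in the model it was 0.468 ± 0.146, which argues against a linear effect of that score as the whole cause. The T cell score only approximates the T cell share, so a change of that share alone is not excluded. RNA handling and library preparation may also move such short RNAs, and stay open because no label gives them.

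CCR9 and GPR15, receptors that guide lymphocytes to the gut, were lower early than before by -1.10 ± 0.15 and -1.16 ± 0.15 on the scale of the scores. Relative to the T cell score of the same library CCR9 was lower by -0.626 ± 0.159 and GPR15 by -0.688 ± 0.148, and relative to the naive T cell score by -0.692 ± 0.152 and -0.755 ± 0.153. These values decide nothing, because both genes were picked for their extreme fall, and single T cell genes also spread around the mean of their list, with IL7R at -0.85 and CD3G at -0.21. CD3G was chosen here after its value was seen. A fall of the T cell share, a loss of gut-homing lymphocytes from blood and a lower expression per cell cannot be told apart here.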

How the results depend on the processing

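The alternatives with the olfactory receptor level in the model, without libraries above 300 CPM on olfactory receptor genes and without libraries above 10% haemoglobin were chosen only after the data were seen.

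Of 126 counts 19 differed from the main value by more than a factor of 1.5, up or down, and each of these is given below. Over 14 alternatives the changed genes ranged from 2555 to 4156 early against before (at least 2284 shared with the main result), from 1947 to 4205 late against before (1642) and from 4498 to 7459 late against early (3856). These ranges leave out each set alone and the minimum fold. Of 4021 values of named genes 3726 kept direction and side of the threshold, 251 lost the call, 39 gained it and 5 reversed. Of 1287 camera values 1214 did so, 49 lost and 22 gained the call, and of 693 list scores 596 did so, 83 lost and 12 gained it.

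Fewer libraries remain in each set alone, but the larger second set gave fewer genes than the first in both comparisons with before. The number of libraries alone thus does not explain the difference between the sets, and its cause was not tested. Early against before 2170 genes changed in the first set and 670 in the second, late against before 1264 and 1098, and late against early 3964 in the second. Genes changed in the same direction at both times numbered 49 and 14, and 30 and 21 list scores passed instead of 48. A fold of at least 1.5 left 454, 653 and 1574 genes, by construction. Camera with an estimated correlation called 0 lists early against before, 0 late against before and 0 late against early. In limma-voom 290 genes changed in the same direction at both times, and 274 with the olfactory receptor level in the model, instead of 181; the cause was not tested.

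With the erythroid score in the model 1947 genes changed late against before and 9 lists late against early. By construction this model removes erythroid differences: ALAS2 turned to 0.21 late against before (adjusted p = 0.304) and 0.00208 late against early (0.994), and the erythroid list turned up in camera, with minus log10 adjusted p at 0.173 (adjusted p = 0.672) and 0.133 (0.736).

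In the first set CD8A was at -0.20 early against before (adjusted p = 0.508) and 0.67 late against early (0.0112), HBG1 at 2.80 late against before (0.00982) and the fetal haemoglobin score at 0.0714 early against before (0.886). That score was 0.0301 (0.921) with the median of the members; the cause was not tested.

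List tests were not run with DESeq2. Libraries of low total limit what can be said of weakly expressed genes.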

Other observations

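All genes in this part were chosen only after their values were seen. Early after transplantation, TIPARP, a target of the aryl hydrocarbon receptor, rose by 0.49 ± 0.07 (adjusted p = 4.46e-08), the death receptor gene FAS by 0.67 ± 0.11 and the kinase gene JAK2 by 0.49 ± 0.09. MMRN1 and EGF, which platelets store, rose by 1.18 ± 0.19 and 1.23 ± 0.22, beside PGRMC1 at 0.74 ± 0.12 and ALDH1A1 at 0.89 ± 0.15. Among genes that fell were PASK at -0.70 ± 0.11, EDAR at -0.78 ± 0.14, GPA33 at -0.68 ± 0.13 and TNFRSF25 at -0.63 ± 0.12.

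Late against before, the ion channel gene MCOLN2 rose by 0.98 ± 0.12 (adjusted p = 5.55e-10), PPP2R2B by 1.14 ± 0.17, the chemokine receptor gene CXCR6 by 0.75 ± 0.14 and the non-coding RNA MIAT by 0.75 ± 0.12. Among genes that fell were ABCG2 at -1.63 ± 0.26, RHAG at -1.78 ± 0.28, BNIP3L at -1.49 ± 0.24 and TFDP1 at -1.38 ± 0.19. Late against early, the T cell kinase gene ZAP70 rose by 0.98 ± 0.11 (adjusted p = 1.43e-12), MYBL1 by 1.09 ± 0.14 and CCR9 by 1.30 ± 0.16. RIOK3 (-2.11 ± 0.25), the ferritin receptor gene NCOA4 (-1.71 ± 0.22), PNP (-1.63 ± 0.19) and HK1 (-1.61 ± 0.19) fell.

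Small non-coding genes took 2.65% of counts before, 2.26% early and 2.95% late (means, SD 1.36, 0.995 and 1.42), and 3.75% in the first set against 2.02% in the second. Within the first set the means were 4.13%, 3.10% and 3.87%, and within the second 1.999%, 1.85% and 2.25%. The late mean thus lay below that from before in the first set and above it in the second. These differences were smaller than the SD over libraries (before and late, 0.978 and 0.957 in the first set, 0.915 and 1.33 in the second) and were not tested.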
